A study of Mus musculus with 2 samples.

How the data were processed

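Gene expression was measured with the 10x Genomics 3' version 3 kit in cells of injured mouse spinal cord, 5 days after injury, in 1 library of cord treated with an HDAC3 inhibitor and 1 library of cord treated with vehicle. The labels name neither the compound nor the number of animals behind a library, and both titles carry the same date. The deposited matrices hold a UMI count per barcode and gene. They were made with Cell Ranger 3.0.2 per the file headers, and mm10, Cell Ranger and Seurat are named per the submitters' processing notes. The matrices list 31053 genes, and the lowest barcode held 501 UMIs in the HDAC3 inhibitor library and 504 in the vehicle library. How reads that match more than 1 gene were treated is not given in the sources used here, so the levels of genes with near-identical copies (Ly6c2, Wfdc17, Stfa2l1, histone and MHC genes, for example) are uncertain.

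Barcodes with at least 500 genes, at least 1000 UMIs and at most 15% mitochondrial UMIs were kept, and 448 of 3423 and 353 of 2523 barcodes failed. Doublets were called per library with Scrublet in scanpy 1.11.5, 26 and 9 barcodes, and left out. The 2951 and 2162 kept cells held 37739599 and 28965341 UMIs, with medians of 9701 and 10214 UMIs per cell. Counts were scaled to 10000 per cell, log-transformed and, for 2000 variable genes, reduced to 30 principal components with both libraries together and no integration. A graph of each cell's 20 nearest neighbours (scikit-learn 1.9.0), weighted by shared neighbours, was clustered with leidenalg 0.10.2 on igraph 0.11.9 at resolution 1 and seed 1 into 33 clusters.

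A cluster took the name of the marker list with the highest mean log2 ratio of its CPM over the median cluster (5 CPM added), if that mean was at least 2.5, at least 0.5 above the next list and resting on at least 3 markers of at least 20 CPM. Clusters whose top genes held more markers of another class, erythroid clusters mixed with another class and clusters of low depth with no marker on top stayed unnamed, and T and NK cells were joined. This named 27 clusters in 15 classes and left 6 unnamed. These thresholds, the rules for leaving clusters unnamed and the joining of T and NK cells were set after the clusters, their marker scores and their cells per library had been seen, but before gene ratios were. The largest monocyte/macrophage-like cluster passed narrowly, with a score of 2.85 against 2.28 for border-associated macrophages. Names end in "-like", since they rest on markers alone.

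UMIs were summed per library and class. Levels are CPM of the class sum with exact Poisson intervals, ratios have exact conditional binomial intervals and shares Clopper-Pearson intervals, all at 95%. Cells of 1 library are not replicates, so no test was made. In the 6 classes with at least 100 cells in each library, genes with at least 100 UMIs over both libraries and at least 50 CPM in the higher library were ranked by ratio, leaving out mitochondrial, ribosomal, haemoglobin and unnamed gene models and 71 duplicated symbols. A gene with over 10 times its CPM in another class was set aside from this ranking as possible free RNA, but stayed in its fixed lists. The naming rule takes the 10 highest and 10 lowest ratios per class, up to 4 most abundant measured members of each list in microglia-like and monocyte/macrophage-like cells, and Hdac3. The text prints these rankings in the myeloid classes just named, the first 5 per side in the other 4 classes, and members of the lists it describes, except that items withheld for evaluation are not reported here. Which lists and members to print was chosen after their values were seen.

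Each fixed list with at least 4 members of at least 20 UMIs was described by the median log2 ratio of its members (0.5 UMI added only where a sum was 0) and by the 95% range of 10000 random lists of the same size, with each member drawn from the 100 genes nearest in expression. Members of a list move together in ways random genes do not, so the range is a description of these libraries. By chance about 1.6 of 32 lists would lie outside in microglia-like cells, where 15 did, and 1.55 of 31 in monocyte/macrophage-like cells, where 10 did. In microglia-like cells these include an endothelial activation list (0.26) and an oligodendrocyte lineage list (-0.42). Lists of other cell types and of sex chromosome genes were not read further in the myeloid classes, a choice made after their values were seen. Groups, markers, gene lists, the cell filter, the naming rule for genes and the alternatives, with the exceptions marked here, were set before the data were examined.

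For the share of cycling cells, cells with at least 2000 UMIs were thinned to 2000 UMIs, a depth set after the clusters were seen, and cells below that were left out. A count of 0 leaves room for 3 UMIs, or 0.574 and 0.457 CPM in microglia-like cells and 0.239 and 0.390 CPM in monocyte/macrophage-like cells. Coordinates are from GENCODE M21 on the same mm10 assembly, matched by gene ID for 246 of 246 named genes. The steps were tested on simulated data. Among microglia-like class sums redrawn with 100 genes changed by 1.50-fold, 99% had a ratio on the right side and 96% an interval that held the true ratio. For 100 genes changed by 2.25-fold these were 100% and 90%, and for 6860 unchanged genes 95.7% of intervals held it. Of 20 lists of 15 genes moved by 1.20-fold, 100% lay outside the random range, as did 7% of 200 lists not moved. These counts were drawn with Poisson error alone, the error that the intervals assume. The simulation therefore does not test how single cells with many UMIs, genes that move together or differences between animals affect the intervals and ranges.

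Alternatives were a looser and a stricter cell filter, doublets kept, Leiden resolutions of 0.5 and 2, genes scaled within each library, classes from each cell's own markers, a median-of-ratios factor, a total without mitochondrial, ribosomal and haemoglobin genes, each cell weighted alike, cells thinned to 1 depth, clusters weighted alike, shares of myeloid cells alone, unthinned shares of cycling cells, and list members with at least 1 or 100 UMIs. The largest cluster of a class alone was added after the data were seen. Gene alternatives were run for the genes named in the report, and not for those of the closing observations. Clusters left unnamed were not compared gene by gene. Classes with at least 50 but under 100 cells in a library were ranked only for the closing observations, and smaller classes not at all. List medians were run under the alternatives for all lists in microglia-like and monocyte/macrophage-like cells, and in the other 4 classes for the lists apart from random lists. Steps not named above used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.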

Results

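Single cells of injured mouse spinal cord, taken 5 days after injury, were compared between 1 library from cord treated with an HDAC3 inhibitor and 1 library from cord treated with vehicle. HDAC3 is the histone deacetylase of the NCoR and SMRT corepressor complexes. The HDAC3 inhibitor library held 3423 barcodes and 38957752 UMIs, with a median of 8243 UMIs per barcode, and the vehicle library 2523 barcodes and 29726813 UMIs, with a median of 8196. After filtering, 2951 and 2162 cells were kept. There is no replicate check with 1 library per group, so libraries, not conditions, are compared below. The 95% intervals cover counting error only, and how far animals of a group differ is unknown. Levels are CPM with all UMIs of a cell class as the total, and values in pairs are in the order HDAC3 inhibitor, vehicle. Ratios are HDAC3 inhibitor over vehicle.

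Hdac3 mRNA (ENSMUSG00000024454, mm10 chromosome 18, 37935844 to 37955016) was low in every class compared, and each interval of its ratio held 1. Microglia-like cells had 15.1 and 16.6 CPM, a ratio of 0.910 (0.673 to 1.23), and monocyte/macrophage-like cells 15.1 and 17.2 CPM, a ratio of 0.880 (0.701 to 1.11). Endothelial-like cells had 28.7 and 28.7 CPM (interval of the ratio 0.725 to 1.38). The ratio was 0.831 (0.555 to 1.25) in oligodendrocyte-like, 0.834 (0.372 to 1.79) in Schwann-like and 0.646 (0.276 to 1.40) in neutrophil-like cells. An inhibitor acts on the enzyme, so this mRNA does not check the treatment. Genes of the HDAC3 corepressor complex had a median log2 ratio inside the range of random lists in microglia-like (-0.093) and monocyte/macrophage-like cells (-0.13), and so had the histone deacetylase genes (-0.19 and -0.058).

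Microglia-like cells made up less, and monocyte/macrophage-like cells more, of the HDAC3 inhibitor library. Microglia-like cells were 15.4% of that library (454 of 2951 cells, Clopper-Pearson 95% interval 14.1 to 16.7) and 22.3% of the vehicle library (482 of 2162 cells, 20.6 to 24.1). Monocyte/macrophage-like cells were 18.1% (16.7 to 19.5) of the HDAC3 inhibitor library, and 282 of 2162 cells (11.7 to 14.5%) in the vehicle library. With classes from each cell's own markers the latter were 7.05% and 5.97%, a ratio of 1.18 (0.944 to 1.48), so that the interval held 1. Of the myeloid cells alone, microglia-like cells were 34.3% and 46.2% and monocyte/macrophage-like cells 40.4% and 27.0%. Neutrophil-like cells were rarer in the HDAC3 inhibitor library, at 5.96% (5.14 to 6.88) and 9.90% (8.67 to 11.2), and with the stricter cell filter the log2 ratio of these shares was -1.28 instead of -0.73. Border-associated macrophage-like cells, which reside at meninges and vessels, were at 4.61% (3.88 to 5.43) and 2.54% (1.92 to 3.30), but at 0.983% and 0.555% at Leiden resolution 2, where the interval of the ratio (0.876 to 3.81) held 1. T/NK-like cells were at 1.73% (1.29 to 2.27) and 0.648% (0.354 to 1.08), from 51 and 14 cells.

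Among glia, oligodendrocyte-like cells were at 10.2% (9.16 to 11.4) and 7.17% (6.12 to 8.34), and their progenitors were lower in the HDAC3 inhibitor library, at 0.847% (0.549 to 1.25) and 2.31% (1.72 to 3.04), from 25 and 50 cells. Of these, 10 and 30 cells were in a cluster with Gpr17, Neu4 and Bmp4 on top. The cluster with Pdgfra and C1ql1 on top held 15 and 20 cells, at 0.508% (0.285 to 0.837) and 0.925% (0.566 to 1.43), with overlapping intervals. Ependymal-like cells, which line the central canal, were at 6.27% (5.42 to 7.20) and 3.38% (2.66 to 4.23), and Schwann-like cells, the myelinating cells of nerve roots, at 4.30% (3.60 to 5.10) and 7.82% (6.72 to 9.03). For endothelial-like cells, at 9.35% (8.33 to 10.5) and 9.90% (8.67 to 11.2), and mural-like cells, at 4.54% (3.82 to 5.36) and 4.02% (3.24 to 4.94), the interval of the ratio held 1. Clusters that the marker rule left unnamed held 14.2% and 12.7% of the cells. Among them was a cluster with endothelial as its best score (7.27), at 4.71% and 4.44% of the libraries. Another was an erythroid cluster mixed with endothelial cells, at 3.52% and 2.13%. Clusters with oligodendrocyte as their best score, at 2.44% and 1.80% and at 0.644% and 0.694%, were also unnamed. The endothelial-like and oligodendrocyte-like shares and levels leave these cells out. Dissociation recovers cell types unequally, and this recovery was not measured.

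**Figure D1:**
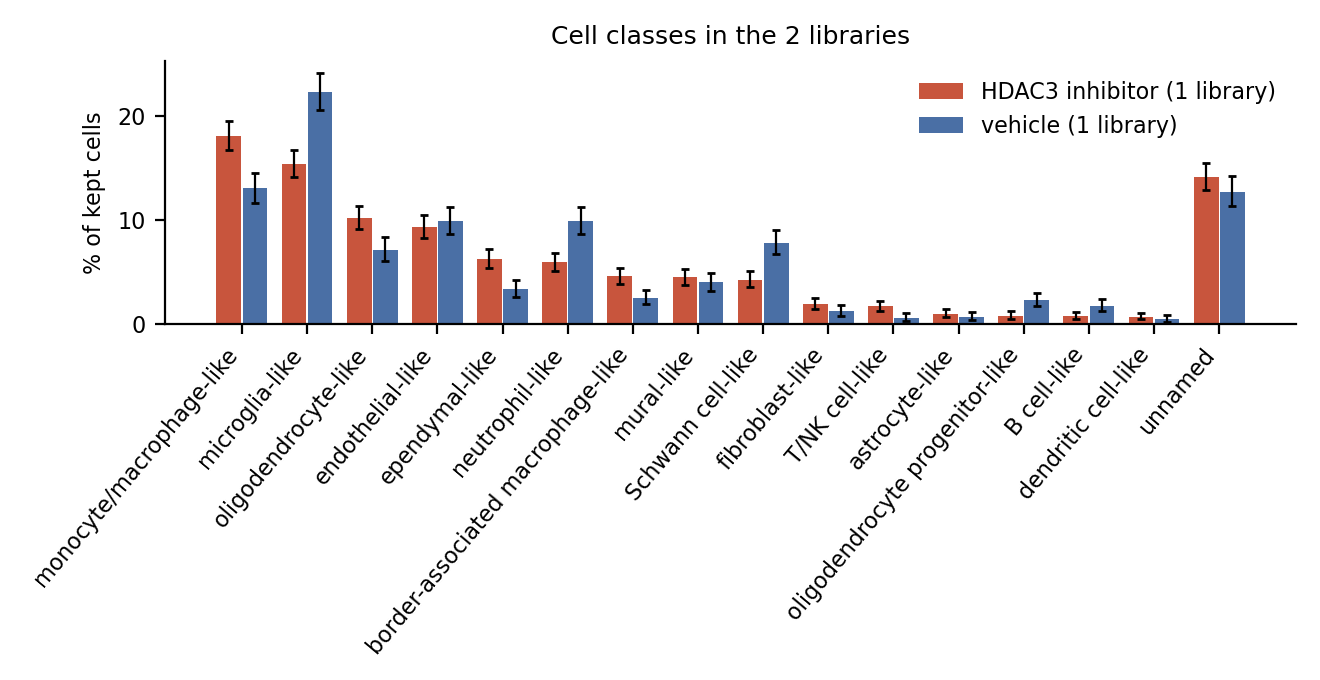
Share of kept cells (%) in each marker-defined cell class, for 1 HDAC3 inhibitor library and 1 vehicle library, with 95% Clopper-Pearson intervals for counting error. Microglia-like cells are at 15.4% and 22.3%, and the HDAC3 inhibitor library has the larger share of monocyte/macrophage-like cells.

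Microglia-like cells of the HDAC3 inhibitor library had lower phagocytic, lysosomal and homeostatic genes and higher DNA replication, sterol synthesis and ribosomal protein genes. All 19 measured members of the phagocytic or disease-associated list were lower, with a median log2 ratio of -0.27 against -0.059 to 0.15 for 95% of random lists of matched expression. For 18 of the 19 the ratio stayed under 1.5-fold. Apoe, a lipid carrier, had 21924 and 29803 CPM, a ratio of 0.736 (0.730 to 0.741). Osteopontin (Spp1) had 13540.1 and 17928 CPM, but was higher in the HDAC3 inhibitor library in the largest microglial cluster (log2 ratio 0.23) and with classes from each cell's own markers (0.039). In that largest cluster, with 68.9% and 65.6% of the class, the list median was -0.026 and inside its random range. The lysosome list had a median of -0.18 (-0.046 to 0.15), with 18 of 20 members lower. It holds the lysosomal proteases cathepsin L (Ctsl), with 3246 and 4588 CPM and a ratio of 0.707 (0.694 to 0.721), cathepsin B (Ctsb, 3517 and 4362 CPM), cathepsin D (Ctsd, 10409.7 and 12031 CPM) and cathepsin S (Ctss, 6003 and 6535 CPM). The homeostatic microglia list had a median of -0.13 (-0.081 to 0.11) and 14 of 17 members lower, but -0.10, inside its range, with classes from each cell's own markers. Lower members were Sparc (ratio 0.885), the CSF1 receptor gene Csf1r (0.865) and Fcrls (0.911).

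DNA replication genes (S phase list) had a median log2 ratio of 0.54 in microglia-like cells (-0.23 to 0.17), with 14 of 16 members higher in the HDAC3 inhibitor library and 8 of them by at least 1.5-fold. With each cell weighted alike the median was 0.020 and inside its random range. A cluster of cycling cells with Mki67 and Top2a on top (53 and 31 cells) was left unnamed. It is in neither the microglia-like nor the monocyte/macrophage-like class. The mitotic G2/M list was at 0.47 (-0.41 to 0.33, 7 of 18 members) and above its range in 9 of 13 alternatives. With classes from each cell's own markers, where 18 members were measured, it was at -0.25, below its range (-0.17 to 0.15). Cyclin D1 (Ccnd1, chromosome 7, 144929931 to 144939925), which drives entry into the cell cycle, had 80.7 and 41.0 CPM, a ratio of 1.97 (1.69 to 2.30). The cholesterol synthesis list had a median of 0.37 (-0.23 to 0.17), with 11 of 14 members higher, and at a thinned depth 0.13, inside its range. Its levels were low. The synthase gene Hmgcs1 had 32.9 and 25.3 CPM, the feedback regulator Insig1 29.5 and 25.6 CPM and Msmo1 23.1 and 18.1 CPM. Ribosomal protein genes had a median of 0.21 (-0.070 to 0.17), with 17 of 18 higher, among them Rpl23 (1.15) and Rpl13 (1.19), with Rps24 at 4381 and 3636 CPM.

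Further lists also lay apart from random lists in microglia-like cells. Interferon response genes had a median of 0.16 (-0.11 to 0.087), with 11 of 20 members higher, but -0.18 in the largest cluster alone, and the median left the high side of its range in 6 of 15 alternatives. The iron and antioxidant list was at 0.19 (-0.11 to 0.12) and at -0.0066 with classes from each cell's own markers. Nuclear genes of oxidative phosphorylation were at 0.10 (-0.086 to 0.074) and at -0.035 with each cell weighted alike. Lower medians were those of the immediate-early genes (-0.13, -0.079 to 0.090), MHC class I genes (-0.12, -0.11 to 0.15) and LXR target genes of lipid efflux (-0.13, -0.11 to 0.12), the last of these at 0.017 at a thinned depth. They stayed below their range in 14 of 15, 11 of 15 and 6 of 15 alternatives, and the iron and nuclear oxidative phosphorylation lists stayed above theirs in 11 of 15 and 11 of 15. The chemokine (0.013), MHC class II (0.029), complement (-0.12), inflammatory cytokine (-0.054), glycolysis (-0.047), mitochondrial (-0.049), phagocytic receptor (-0.051), alternative activation (-0.012), trophic factor (-0.078) and extracellular matrix (0.087) lists lay inside their random ranges. Some left their range under alternatives, among them the complement (5 of 15), inflammatory cytokine (4 of 15) and extracellular matrix lists (3 of 15).

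Among single genes, the highest ratio in microglia-like cells was that of Rsad2, which encodes the antiviral protein viperin (chromosome 12, 26442746 to 26456452), with 53.4 and 23.9 CPM and a ratio of 2.23 (1.83 to 2.73), though its log2 ratio was -0.052 in the largest cluster alone. After Rsad2 and Ccnd1 came Selenoh (1.58), the adhesion gene Vcam1 (1.51), Pilra (1.51), Dctpp1 (52.2 and 34.9 CPM), Wfdc17 (1.48, but log2 ratio -0.18 at a thinned depth), the TNF family ligand Tnfsf9 (1.42), C1qbp (1.38) and Tmx4 (1.36). The lowest ratio was that of the apolipoprotein gene Apoc1 (chromosome 7, 19689481 to 19692660), with 156 and 343 CPM and a ratio of 0.455 (0.420 to 0.494), and a single vehicle cell held 19.9% of its vehicle UMIs. Next were Rbpms (0.522), the mannosidase gene Man2b2 (0.607), the collagen gene Col27a1 (0.640), the integrin gene Itga6 (0.646), the MHC class II ligand gene Lag3 (0.646), the cytokine receptor subunit Csf2rb (0.652), the homeobox gene Hhex (0.694), Ints6 (0.697) and the chemokine receptor gene Cxcr4 (0.704).

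Monocyte/macrophage-like cells of the HDAC3 inhibitor library had higher chemokine, interferon response, iron handling and glycolytic genes. The chemokine list had a median log2 ratio of 0.55 (random lists -0.11 to 0.14), with 10 of 14 members higher, 7 of them by at least 1.5-fold, and stayed above the range in all 15 alternatives. The monocyte attractant Ccl2 (chromosome 11, 82035571 to 82037453) had 80.3 and 30.6 CPM, a ratio of 2.63 (2.28 to 3.04). The neutrophil attractant Cxcl2 had 125 and 67.3 CPM, a ratio of 1.86 (1.68 to 2.06), but its level in another class was over 10 times as high, so free RNA is not ruled out. Cxcl14 had a ratio of 1.78, Cxcl16 had 145 and 121 CPM, and the ratio of Ccl3, at 1.03 (0.949 to 1.13), had an interval that held 1. Ccl6 had a ratio of 0.868, but its log2 ratio was 0.52 with clusters weighted alike, 0.25 in the largest cluster alone and 0.013 at a thinned depth. Platelet factor 4 (Pf4, chromosome 5, 90772435 to 90773383), a further chemokine, had 267 and 113 CPM, a ratio of 2.36 (2.19 to 2.55). Pf4 is also on the marker list of border-associated macrophages, and whether its level follows the mix of macrophage types was not tested.

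Interferon response genes had a median of 0.32 in monocyte/macrophage-like cells (-0.089 to 0.11), with 16 of 20 members higher, 7 by at least 1.5-fold, but 0.091 with own-marker classes and 0.10 at a thinned depth, both inside the range. Irf7, a transcription factor of that response, had 78.7 and 51.6 CPM, a ratio of 1.52 (1.36 to 1.72), and the ubiquitin-like gene Isg15 144 and 97.4 CPM, a ratio of 1.48 (1.36 to 1.62). Bst2 was higher (ratio 1.19), while Ifitm3 (0.899), Ifi27l2a (0.933) and Slfn2 (0.919) were lower, but higher in the largest cluster alone (log2 ratios 0.45, 0.86 and 0.14) and with clusters weighted alike. Without the 5% of cells with the most list UMIs in each library, the list median was 0.11 and inside its range. The iron and antioxidant list had a median of 0.24 (-0.13 to 0.11), with 10 of 14 members higher, and lay inside the range with each cell weighted alike (0.10), at a thinned depth (0.084) and with clusters weighted alike (0.075). Haem oxygenase (Hmox1, chromosome 8, 75093621 to 75100589) had 437 and 281 CPM, a ratio of 1.56 (1.48 to 1.64), the ferritin genes Fth1 and Ftl1 ratios of 1.28 and 1.19, the peroxiredoxin Prdx1 1.19 and the metallothionein Mt1 0.989 (0.947 to 1.03).

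Glycolysis genes had a median of 0.18 (-0.074 to 0.12) in monocyte/macrophage-like cells, with 13 of 16 members higher in the HDAC3 inhibitor library, including Gapdh (1.16), Pgam1 (1.17), Pkm (1.19) and Ldha (1.21), but the median lay inside the range at Leiden resolution 2 (0.12) and at a thinned depth (0.12). The 13 respiratory genes of the mitochondrial genome were on the other side, with a median of -0.24 (-0.10 to 0.10) and 11 lower, among them mt-Co3 (0.775), mt-Atp6 (0.832), mt-Co1 (0.847) and mt-Co2 (0.889). Random lists matched to the phagocytic or disease-associated list were centred below 0 here, with a median of -0.058 and a range of -0.10 to 0.021. That list, lower in microglia-like cells, lay above this range at 0.062, with 12 of 19 members higher. Its abundant members lay on both sides. Spp1 had 39234 and 28357 CPM, a ratio of 1.38 (1.38 to 1.39), and Ctsd a ratio of 1.04, though its log2 ratio was -0.0045 with clusters weighted alike and -0.0028 in the largest cluster alone. Apoe (62573 and 72576 CPM, ratio 0.862) and the lysozyme gene Lyz2 (0.859) were lower. Further genes among the highest ratios were the scavenger receptors Msr1 (1.74) and Cd36 (1.44), the lipoprotein lipase gene Lpl (1.46) and the chaperone gene Fkbp2 (1.44). The phagocytic receptor list had a median of -0.093 (-0.076 to 0.13), but 0.20 with classes from each cell's own markers, and the cholesterol synthesis list -0.24 (-0.21 to 0.18), but 0.059 in the largest cluster alone. They stayed below their range in 8 of 15 and 9 of 15 alternatives.

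Among the lowest ratios in monocyte/macrophage-like cells were those of monocyte genes. Plac8 (chromosome 5, 100553725 to 100572245) had 159 and 307 CPM, a ratio of 0.519 (0.488 to 0.551), and the monocyte surface gene Ly6c2 121 and 203 CPM, a ratio of 0.594 (0.553 to 0.638), but both were higher in the largest cluster alone (log2 ratios 0.64 and 0.81) and Plac8 also with clusters weighted alike (0.057). That largest cluster held 90.1% and 83.7% of the class, and a smaller cluster with Plac8, Ccr2 and Ly6c2 but also the granulocyte and monocyte progenitor genes Prtn3, Elane, Ctsg and Mpo among its top genes held 4.49% and 13.8%, so progenitors from marrow are not ruled out. Also low were the peroxidase gene Gpx3 (0.570), Cytip (0.577), the oxidative stress regulator Nfe2l2 (0.667), Glipr1 (0.679) and the DNA methyltransferase gene Dnmt3a (0.687). The integrin gene Itgax had a ratio of 0.634, but log2 ratios of 0.20 with the stricter cell filter, 0.0016 at Leiden resolution 2 and 0.23 at a thinned depth. The proton pump gene Atp6v0d2 had a ratio of 0.642, but log2 ratios of 0.47 with the stricter filter and 0.12 at that resolution.

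Antigen presentation genes of MHC class II were lower in monocyte/macrophage-like cells of the HDAC3 inhibitor library, with a median of -0.67 (-0.15 to 0.17) and 7 of 7 members lower, but the median was 0.052 with the stricter cell filter, 0.17 with classes from each cell's own markers and 0.10 in the largest cluster alone. The invariant chain gene Cd74 had 97.4 and 154 CPM, but log2 ratios of 0.15 with the stricter filter and 0.33 with own-marker classes. The peptide loading genes H2-DMa and H2-DMb1 had 62.6 and 67.1 CPM and 44.8 and 49.1 CPM, and Ctss 5805 and 6083 CPM, lower, but at a log2 ratio of 0.13 with own-marker classes. The G2/M list, measured without the unnamed cycling cluster, was lower too, at -1.18 (-0.38 to 0.37, 10 of 11 members). It was, however, at 0.44 in the largest cluster alone, where 5 members were measured. It lay inside its range with the looser cell filter (-0.10) and with doublets kept (-0.36), and below it in 10 of 13 alternatives. The S phase (-0.14), MHC class I (-0.061), lysosome (-0.013), homeostatic (-0.030), complement (0.067), ribosomal protein (-0.071), inflammatory cytokine (0.0043), LXR target (0.0025), nuclear oxidative phosphorylation (0.10), immediate-early (0.0090), alternative activation (-0.016), trophic factor (0.10) and extracellular matrix (0.027) lists lay inside their random ranges. Under alternatives some of these left their range, among them the extracellular matrix (5 of 15), homeostatic (3 of 15) and nuclear oxidative phosphorylation lists (2 of 15).

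**Figure D2:**
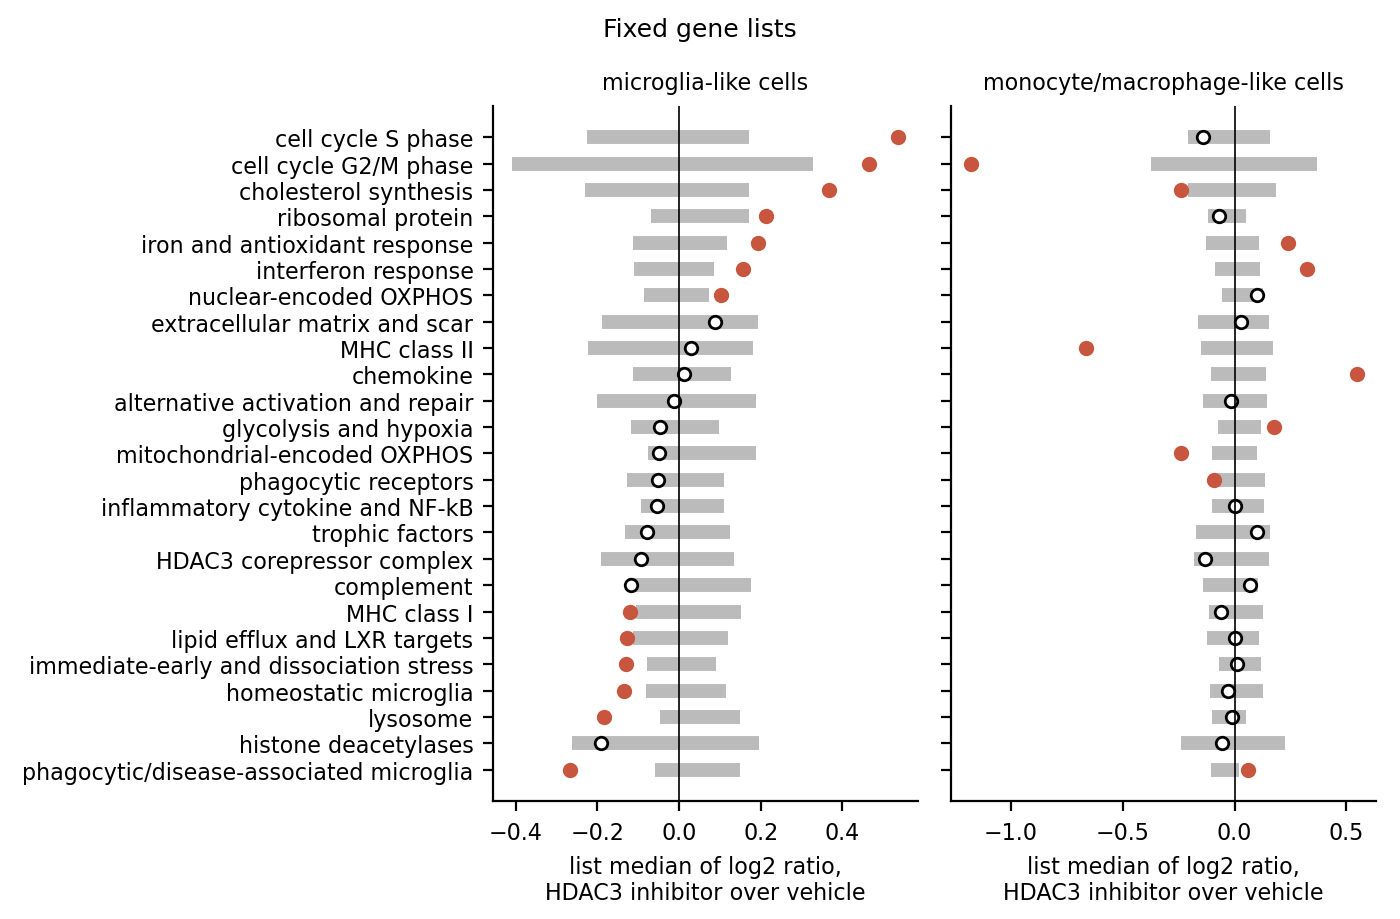
Median log2 ratio (HDAC3 inhibitor over vehicle) of the measured members of each fixed gene list in microglia-like and monocyte/macrophage-like cells, 1 library per group, with grey bars for 95% of 10000 random lists of matched expression and filled points outside them. The phagocytic or disease-associated list is at -0.27 in microglia-like and 0.062 in monocyte/macrophage-like cells, and the chemokine list at 0.55 in the latter.

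Few microglia-like or monocyte/macrophage-like cells held a UMI of the proliferation genes Mki67 or Top2a once each cell was thinned to 2000 UMIs. The shares were 1.15% (5 of 435 cells, 0.374 to 2.66) and 0.871% (4 of 459 cells, 0.238 to 2.22) in microglia-like cells. They were 2.44% (13 of 532 cells, 1.31 to 4.14) and 1.06% (3 of 282 cells, 0.220 to 3.08) in monocyte/macrophage-like cells. Oligodendrocyte-like cells, which should lack both genes, had 0% (0 of 301 cells, 0 to 1.22) and 0.645% (1 of 155 cells, 0.0163 to 3.54). Median depths before thinning were 10404 and 14420 UMIs in oligodendrocyte-like, 10801 and 12404 in microglia-like and 23482.5 and 26030.5 in monocyte/macrophage-like cells. Unthinned, the shares were 6.17% and 5.60% in microglia-like cells and, on the other side, 18.4% and 20.9% in monocyte/macrophage-like cells, and at both depths the interval of the ratio held 1 in both classes. The marker rule left a cluster of cycling cells unnamed, at 1.80% and 1.43% of the libraries, because its scores for microglia (3.97) and monocytes/macrophages (3.48) were too close. Together with it, both classes had shares of 5.50% (56 of 1019 cells, 4.18 to 7.08) and 3.12% (24 of 768 cells, 2.01 to 4.61), a ratio of 1.76 (1.07 to 2.97), and 16.7% and 14.0% unthinned, where the interval of the ratio (0.938 to 1.53) held 1. Adding this cluster was chosen after the data were seen.

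Oligodendrocyte-like cells of the HDAC3 inhibitor library had higher cholesterol synthesis genes. Their immediate-early genes were lower, but some of these were set aside as possible free RNA. The cholesterol list had a median log2 ratio of 0.44 (-0.072 to 0.12), with 13 of 16 members higher. Idi1 (chromosome 13, 8885501 to 8892451), an isomerase of the isoprenoid steps, had 235 and 146 CPM, a ratio of 1.62 (1.42 to 1.84). The linker histone genes Hist1h1e (1.64) and Hist1h1c (1.59) and the galactokinase gene Galk1 (1.62) were also among the highest. Lowest were the growth arrest genes Gadd45a (0.522) and Gadd45b (0.589), the protease gene Klk8 (0.528), the acute-phase gene Serpina3n (0.548, 0.510 to 0.588) and Zfp579 (0.571), with 51.4% of the Klk8 UMIs of the HDAC3 inhibitor library in a single cell. The class is a single cluster. Unnamed clusters with oligodendrocyte as their best score had Klk6 and Serpina3n, or Klk8, among their top genes. They are outside the class, so these lower levels hold for the named cluster alone. The immediate-early list had a median of -0.26 (-0.13 to 0.10), and -0.073, inside its range, at a thinned depth. It includes Atf3 (12.1 and 75.6 CPM), Zfp36 (22.7 and 55.2 CPM) and Junb (100 and 180 CPM), set aside in this class as possible free RNA. Chemokine genes had a median of -1.40, from 4 members, and free RNA was not tested as an account of it. The complement list was at -1.67, but at 0.027 with the stricter cell filter, the homeostatic microglia list at -0.66, but at 0.13 with that filter and 0.10 with own-marker classes, and the lysosome list at -0.24, but at 0.036 with own-marker classes. UMIs of 5 macrophage genes (Spp1, Gpnmb, Fabp5, Lgals3 and Lyz2) per oligodendrocyte-like cell were 33.2 and 48.9, or 3034 and 3220 CPM.

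Endothelial-like cells of the HDAC3 inhibitor library had higher Lrg1, which encodes a secreted angiogenic protein (chromosome 17, 56119678 to 56122001), with 353 and 152 CPM and a ratio of 2.33 (2.07 to 2.62), and a higher level of the peptidase gene Lap3, with 112 and 50.1 CPM and a ratio of 2.25. The interferon-induced genes Cxcl10 (6.21) and Rsad2 (2.84) had higher ratios, but a single cell held 85.3% and 59.8% of their UMIs in that library. Myof had a ratio of 1.69, but log2 ratios of -0.37 at a thinned depth and -0.22 in the largest cluster alone. Lowest were Scgb3a1 (0.413, 0.342 to 0.496), the Notch target Hes1 (460.1 and 811 CPM, ratio 0.567, 0.530 to 0.608), Amotl2 (0.581), the tissue plasminogen activator gene Plat (0.599) and Bloc1s1 (0.604). The ribosomal protein list was at 0.13 (-0.062 to 0.088) and the chemokine list at 0.31 (-0.22 to 0.23), but the latter at -0.0075 with the stricter cell filter and -0.0048 at Leiden resolution 2, and above its range in 9 of 14 alternatives. The cholesterol synthesis list had a median of -0.39 (-0.25 to 0.20), with 14 of 16 members lower, opposite in sign to oligodendrocyte-like cells, but 0.12 at a thinned depth.

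Neutrophil-like cells of the HDAC3 inhibitor library had lower interferon response genes, with a median of -0.49 (-0.091 to 0.27) and 17 of 19 members lower. The chemokine receptor gene Ccr1 had 263 and 571 CPM, a ratio of 0.460 (0.403 to 0.524). With it among the lowest were the stefin gene Stfa2l1 (0.392), the NF-kB inhibitor Tnfaip3 (0.466) and Stk39 (0.476). The granule protease gene Elane had a ratio of 0.459, but a log2 ratio of 0.30 in the largest cluster alone, and a single vehicle cell held 94.4% of its vehicle UMIs. Highest were Gngt2 (4.98, but log2 ratio -0.96 in the largest cluster alone), Ifitm1 (2.64, 2.25 to 3.09), Sde2 (2.46), Samd4b (2.46) and Wfdc17 (2.36). The ribosomal protein (0.37), G2/M (0.63) and iron lists (0.32, but -0.032 with the stricter cell filter) had higher medians. The ribosomal protein list lay inside its range in the largest cluster alone (0.11) and at a thinned depth (0.23), the G2/M list with each cell weighted alike (0.20), and the iron list stayed above its range in 11 of 15 alternatives. The cholesterol list had a lower median (-0.60). A cluster with the immature granule genes Ltf and Ngp on top held 38.1% and 53.3% of the class, and whether its cells came from cord, blood or marrow taken along was not tested, so the neutrophil share and the levels of the class carry the same doubt. Median depth was 4076.5 and 6878.5 UMIs per cell, and UMIs of the 5 macrophage genes per cell were 91.5 and 154.

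Schwann-like cells of the HDAC3 inhibitor library had lower immediate-early and stress genes, with a median of -0.41 (-0.10 to 0.19) and 16 of 19 members lower. The stress-induced gene Ddit4 had 94.9 and 197 CPM, a ratio of 0.483 (0.330 to 0.694), followed by Zdhhc8 (0.511), the BMP antagonist gene Chrdl1 (0.528), the EGFR inhibitor gene Errfi1 (0.530) and the MAP kinase phosphatase gene Dusp1 (0.535). The transcription factor gene Cebpd (chromosome 16, 15887286 to 15891031) had 396 and 132 CPM, a ratio of 3.01 (2.29 to 3.98), and after it came Isg15 (2.39), Tbrg1 (1.89), Fxyd3 (1.85) and the vimentin gene Vim (1.78), with 31.8% of the Vim UMIs of that library in a single cell. The ribosomal protein (0.24) and nuclear oxidative phosphorylation lists (0.24) had higher medians and the myelin list a lower median (-0.19). At a thinned depth the ribosomal protein (0.13) and myelin lists (-0.077) lay inside their ranges, and the myelin list stayed below its range in 11 of 15 alternatives. The immediate-early list was also lower in endothelial-like cells (-0.21), but 0.0089 with the stricter cell filter, 0.015 and 0.034 at the other Leiden resolutions and 0.0015 with own-marker classes, and dissociation is known to induce these genes.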

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

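Readings with the clusters weighted alike, and all readings of free RNA except the test of MHC class II in monocyte/macrophage-like cells, were chosen after the results were seen. Several lists lay above their random range in 1 cell class and below it in another, which marked them for a closer look, and the difference between classes was not tested for any of them. The medians differed by 7.67 for MHC class II (neutrophil-like 4.89, Schwann-like -2.77), from few UMIs (25 in neutrophil-like cells of the vehicle and 27 in Schwann-like cells of the HDAC3 inhibitor library). They differed by 1.94 for chemokine genes (monocyte/macrophage-like 0.55, oligodendrocyte-like -1.40 from 4 members). Free RNA was not tested for the latter. In oligodendrocyte-like cells C1qa (13.3 and 69.2 CPM), C1qb (22.7 and 57.3 CPM) and Ctss (20.6 and 73.0 CPM) were set aside as possible free RNA. For G2/M genes the difference was 1.81 (neutrophil-like 0.63, monocyte/macrophage-like -1.18, but 0.44 in its largest cluster alone and -0.10 with the looser cell filter) and for cholesterol synthesis 1.04 (oligodendrocyte-like 0.44, neutrophil-like -0.60). It was 0.81 for interferon genes (monocyte/macrophage-like 0.32, neutrophil-like -0.49), 0.54 for phagocytic receptors (neutrophil-like 0.45, monocyte/macrophage-like -0.093, but 0.20 with own-marker classes) and 0.33 for the phagocytic list (monocyte/macrophage-like 0.062, microglia-like -0.27). Free RNA at the level per oligodendrocyte-like cell (0.0695 and 0.103 UMIs) did not account for the MHC class II medians in neutrophil-like (1.39 and 0.117 UMIs per cell) or Schwann-like cells (0.213 and 0.817), and RNA of other cells captured together was not tested.

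For the lower phagocytic list in microglia-like cells, a difference in depth did not account for the whole of it, since the median at a thinned depth was -0.16, below the range of -0.075 to 0.16. For a different mix of clusters the readings disagreed. In the largest cluster alone, the test set before its result was seen, the median was -0.026 and inside its range (-0.10 to 0.14), which that explanation predicts, while with clusters weighted alike it was -0.18 and below its range (-0.074 to 0.13). The latter weighs clusters of 58 and 70, 53 and 69, and 30 and 27 cells like the largest, of 313 and 316 cells, so it does not decide the question. UMIs of 5 macrophage genes per cell were 33.2 and 48.9 in oligodendrocyte-like cells, a ratio of 0.679 (0.659 to 0.700). That class held 10954 and 15196 UMIs per cell, and the 5 genes were at 3034 and 3220 CPM. This ratio therefore cannot be told apart from the difference in depth. In endothelial-like cells the UMIs of the 5 genes per cell were 3.16 and 2.71, a ratio of 1.17 (1.05 to 1.30). After the UMIs per oligodendrocyte-like cell were taken away, the list median was -0.34 (-0.13 to 0.20), and after those per neutrophil-like cell -0.28 (-0.073 to 0.19). Neutrophil-like cells held 91.5 and 154 UMIs of the 5 genes per cell, which can include their own expression. Free RNA at the levels taken away did not account for the list, but how much of these levels is free RNA was not measured. Whether the inhibitor or the animals account for this list was not tested.

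For the lower MHC class II list in monocyte/macrophage-like cells, the mix of clusters gave readings of both kinds, 0.10 in the largest cluster alone, inside its range (-0.16 to 0.19), as that explanation predicts, and -0.87 with clusters weighted alike, below its range (-0.15 to 0.18). The second reading weighs clusters of 24 and 39 and of 29 and 7 cells like the largest, of 481 and 236 cells. It rests mostly on few cells, so it does not decide against that explanation. Free RNA did not account for the lower list, as vehicle exceeded HDAC3 inhibitor by 0.0337 MHC class II UMIs per oligodendrocyte-like cell (upper limit 0.125) and by 4.35 per monocyte/macrophage-like cell. The inhibitor as a cause was not tested.

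For the higher interferon list in monocyte/macrophage-like cells, the mix of clusters did not account for the median, which was 0.59 in the largest cluster alone (range -0.077 to 0.14) and 0.40 with clusters weighted alike (-0.077 to 0.14). A few cells with very high levels stayed open as an account, since without the 5% of cells with the most list UMIs in each library (27 and 15 cells) the median was 0.11 and inside its range (-0.10 to 0.13). Why those cells were high, and whether the inhibitor raised them, was not tested. The lower G2/M median in the same class was measured without the unnamed cycling cluster. It was 0.44 in the largest cluster alone (-0.43 to 0.59) and -0.61 with clusters weighted alike (-0.36 to 0.43), which weighs the small clusters like the largest. It lay inside its range with the looser cell filter (-0.10) and with doublets kept (-0.36), and below it in 10 of 13 alternatives.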

How the results depend on the processing

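The largest cluster alone was chosen after the data were seen. No paired analysis was possible because each group has 1 library. A median-of-ratios factor and a total without mitochondrial, ribosomal and haemoglobin genes shift all genes of a class alike. A list then moves together with its random range, so under each all 51 medians stayed apart and could not do otherwise. In oligodendrocyte-like and Schwann-like cells, each class a single cluster, the largest cluster alone and clusters weighted alike repeat the main value. Counts of alternatives here and above include these settings. Medians that stayed on the same side of their random range under all alternatives that gave a value were those of these lists: chemokine (0.42 to 0.89), phagocytic (0.028 to 0.23) and mitochondrial (-0.27 to -0.18) in monocyte/macrophage-like cells, and lysosome (-0.23 to -0.12) and ribosomal protein (0.16 to 0.26) in microglia-like cells. In the other classes they were chemokine (-1.40 to -0.87) and cholesterol (0.31 to 0.47) in oligodendrocyte-like cells, ribosomal protein (0.090 to 0.14) in endothelial-like cells, interferon (-0.98 to -0.15), MHC class II (up to 5.16) and cholesterol (-1.20 to -0.34) in neutrophil-like cells and MHC class II (-3.55 to -1.22), nuclear OXPHOS (0.19 to 0.30) and immediate-early (-0.45 to -0.31) in Schwann-like cells. Of the gene values under alternatives, 1263 stayed within the counting interval, 423 left it on the same side and 30 changed side. Of the medians of lists apart from random lists, 626 stayed apart, 80 came inside and 29 changed sign, and 59 shares stayed and 2 moved.

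A looser cell filter put inside the random range the G2/M (-0.10) and cholesterol (-0.12) lists in monocyte/macrophage-like cells and the chemokine (0.15) list in endothelial-like cells. A stricter cell filter put inside the random range the LXR (-0.10) list in microglia-like cells and the phagocytic receptor (0.17) and myelin (-0.49) lists in neutrophil-like cells, turned the sign of the MHC class II (0.052) list in monocyte/macrophage-like cells, Itgax (0.20), Atp6v0d2 (0.47) and Cd74 (0.15) in monocyte/macrophage-like cells, the chemokine (-0.0075) and immediate-early (0.0089) lists in endothelial-like cells, the iron (-0.032) list in neutrophil-like cells and the homeostatic (0.13), phagocytic (0.034) and complement (0.027) lists in oligodendrocyte-like cells and moved the log2 share ratio of neutrophil-like cells to -1.28. Keeping doublets put inside the random range the interferon (0.092) and LXR (-0.042) lists in microglia-like cells and the G2/M (-0.36) and phagocytic receptor (-0.073) lists in monocyte/macrophage-like cells and turned the sign of the phagocytic (0.33) list in oligodendrocyte-like cells. Leiden resolution 0.5 put inside the random range the interferon (0.049) and LXR (-0.030) lists in microglia-like cells and the chemokine (0.0037) list in endothelial-like cells and turned the sign of the immediate-early (0.015) list in endothelial-like cells. Leiden resolution 2 put inside the random range the glycolysis (0.12) list in monocyte/macrophage-like cells and turned the sign of Itgax (0.0016) and Atp6v0d2 (0.12) in monocyte/macrophage-like cells and the chemokine (-0.0048) and immediate-early (0.034) lists in endothelial-like cells. Scaling genes within each library put inside the random range the interferon (0.046) and LXR (-0.026) lists in microglia-like cells, the phagocytic receptor (-0.063) list in monocyte/macrophage-like cells, the chemokine (0.16) list in endothelial-like cells and the phagocytic receptor (0.41) list in neutrophil-like cells. Classes from each cell's own markers put inside the random range the homeostatic (-0.10), LXR (-0.13), nuclear OXPHOS (0.078) and immediate-early (-0.087) lists in microglia-like cells, the interferon (0.091) and cholesterol (-0.24) lists in monocyte/macrophage-like cells and the complement (-0.031) list in oligodendrocyte-like cells. This setting also turned the sign of the G2/M (-0.25) and iron (-0.0066) lists in microglia-like cells, Spp1 (0.039) in microglia-like cells, the MHC class II (0.17) and phagocytic receptor (0.20) lists in monocyte/macrophage-like cells, Ctss (0.13) and Cd74 (0.33) in monocyte/macrophage-like cells, the immediate-early (0.0015) and myelin (0.11) lists in endothelial-like cells and the homeostatic (0.10), phagocytic (0.020) and lysosome (0.036) lists in oligodendrocyte-like cells and moved the log2 share ratio of monocyte/macrophage-like cells to 0.24. Weighting each cell alike put inside the random range the MHC class I (-0.054), S phase (0.020), G2/M (0.35) and LXR (-0.020) lists in microglia-like cells, the phagocytic receptor (-0.054) and iron (0.10) lists in monocyte/macrophage-like cells, the cholesterol (-0.30) list in endothelial-like cells, the G2/M (0.20) and iron (0.32) lists in neutrophil-like cells and the reactive astrocyte (0.37) and myelin (-0.12) lists in Schwann-like cells and turned the sign of the nuclear OXPHOS (-0.035) list in microglia-like cells. Thinning cells to 1 depth put inside the random range the interferon (0.077), MHC class I (-0.12), cholesterol (0.13), nuclear OXPHOS (0.067) and iron (0.029) lists in microglia-like cells, the interferon (0.10), cholesterol (-0.20), glycolysis (0.12) and iron (0.084) lists in monocyte/macrophage-like cells, the MHC class I (-0.18) and ribosomal protein (0.23) lists in neutrophil-like cells, the phagocytic (-0.12), lysosome (-0.043) and immediate-early (-0.073) lists in oligodendrocyte-like cells and the ribosomal protein (0.13) and myelin (-0.077) lists in Schwann-like cells. At that depth it also turned the sign of the LXR (0.017) list in microglia-like cells, Wfdc17 (-0.18) in microglia-like cells, the phagocytic receptor (0.0066) list in monocyte/macrophage-like cells, Itgax (0.23) and Ccl6 (0.013) in monocyte/macrophage-like cells, the cholesterol (0.12) list in endothelial-like cells and Myof (-0.37) in endothelial-like cells. Weighting clusters alike put inside the random range the interferon (0.053), MHC class I (-0.079), G2/M (0.30), LXR (-0.061), nuclear OXPHOS (0.034) and iron (0.091) lists in microglia-like cells, the phagocytic receptor (-0.057) and iron (0.075) lists in monocyte/macrophage-like cells and the myelin (-0.31) list in neutrophil-like cells. Such weights also turned the sign of the cholesterol (0.00056) list in monocyte/macrophage-like cells and Plac8 (0.057), Ctsd (-0.0045), Ccl6 (0.52), Ifitm3 (0.30), Ifi27l2a (0.36) and Slfn2 (0.074) in monocyte/macrophage-like cells. The largest cluster alone put inside the random range the phagocytic (-0.026), MHC class I (-0.091), G2/M (0.0031), LXR (-0.057) and iron (0.066) lists in microglia-like cells and the MHC class I (-0.14), complement (-0.10), ribosomal protein (0.11) and iron (0.30) lists in neutrophil-like cells. That cluster also turned the sign of the interferon (-0.18) list in microglia-like cells, Rsad2 (-0.052) and Spp1 (0.23) in microglia-like cells, the MHC class II (0.10), G2/M (0.44) and cholesterol (0.059) lists in monocyte/macrophage-like cells, Plac8 (0.64), Ly6c2 (0.81), Ctsd (-0.0028), Ccl6 (0.25), Ifitm3 (0.45), Ifi27l2a (0.86) and Slfn2 (0.14) in monocyte/macrophage-like cells, Myof (-0.22) in endothelial-like cells and Gngt2 (-0.96) and Elane (0.30) in neutrophil-like cells. List members with at least 1 UMI put inside the random range the iron (0.16) and myelin (-0.25) lists in neutrophil-like cells, the phagocytic (-0.14) list in oligodendrocyte-like cells and the reactive astrocyte (0.47) and myelin (-0.15) lists in Schwann-like cells. List members with at least 100 UMIs put inside the random range the cholesterol (-0.028) and phagocytic receptor (-0.065) lists in monocyte/macrophage-like cells, the cholesterol (-0.14) list in endothelial-like cells and the myelin (-0.15) list in Schwann-like cells. The cause was not tested for any of these. A list with under 4 measured members under an alternative gave no value. How far depth limits each list was not compared.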

Other observations

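Genes of the smaller classes were ranked by the same rule, a choice made after the data were seen. Border-associated macrophage-like cells of the HDAC3 inhibitor library had lower Klf2, a factor of quiescence (308 and 782 CPM, ratio 0.394, 0.348 to 0.445), and higher levels of the neutrophil attractant Cxcl1 (499 and 193 CPM, ratio 2.59, 2.16 to 3.11). The basophil and mast cell genes Prss34, Mcpt8 and Cpa3 had ratios of 7.61, 5.96 and 3.62, with 53.3%, 55.5% and 62.9% of the UMIs of the HDAC3 inhibitor library in a single cell. All UMIs of each gene came from 2 cells of that library and, in the same order, from 1, 2 and 2 cells of the vehicle library. The protease inhibitor gene Slpi had 31.7 and 567 CPM, with 90.1% of its vehicle UMIs in a single cell. Ependymal-like cells had higher levels of the clock-controlled gene Dbp (139.6 and 62.6 CPM, ratio 2.23, 1.53 to 3.35) and lower levels of the actin-binding gene Actn1 (68.9 and 152 CPM, ratio 0.454, 0.329 to 0.628). Mural-like cells had lower Ifi27l2a (10.4 and 187 CPM) and Ccl2 (52.1 and 512 CPM), with 89.3% of the vehicle Ccl2 UMIs in a single cell, and higher Id1 (212 and 80.1 CPM), a BMP target.

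Within classes, a B cell cluster with the precursor genes Vpreb1 and Vpreb3 on top held 3 and 20 cells, and whether marrow taken along with the cord was their origin was not tested. A monocyte cluster with Ear2, Treml4 and Ace on top, genes of patrolling monocytes, held 29 and 7 cells. The neutrophil cluster with Ltf and Ngp on top held 67 and 114 cells. MHC class II genes, absent from most neutrophils, had 1.39 and 0.117 UMIs per neutrophil-like cell, from 245 and 25 UMIs in all. Free RNA at the level of other classes did not account for this, since the same genes had 0.0695 and 0.103 UMIs per oligodendrocyte-like and 0.116 and 0.136 per endothelial-like cell, while RNA of another cell captured together was not tested. The myelin list had a median of -0.63 in endothelial-like cells (-0.24 to 0.23), but 0.11 with own-marker classes, and -0.49 in neutrophil-like cells, below its range in 9 of 12 alternatives. Other lists apart from random lists were MHC class I (-0.13, but inside its range at -0.14 in the largest cluster alone), complement (-0.32, but inside at -0.10 there) and phagocytic receptors (0.45, but inside at 0.17 with the stricter cell filter) in neutrophil-like cells. Further ones were MHC class II (-2.77) and reactive astrocyte genes (0.78, but inside at 0.37 with each cell weighted alike) in Schwann-like cells and the phagocytic list in oligodendrocyte-like cells (-0.14, but 0.33 with doublets kept, 0.034 with the stricter cell filter and 0.020 with own-marker classes).

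RNA of other cell types differed between the libraries, but not alike in all classes. Haemoglobin UMIs per cell were 0.256 and 4.53 in microglia-like, 0.182 and 12.0 in neutrophil-like and 0.0866 and 3.96 in Schwann-like cells, but 4.05 and 2.52 in endothelial-like cells. They were 0.219 and 0.329 in oligodendrocyte-like and 0.648 and 0.493 in monocyte/macrophage-like cells. The haemoglobin difference thus varied by class and was not a level shared by all cells of a library, and its source was not tested. UMIs of neutrophil genes per oligodendrocyte-like cell were 0.791 and 2.03. Neither library held a UMI of the female-specific transcript Xist, and the Y-linked gene Ddx3y had 2137 and 1778 UMIs.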
